A study of Mus musculus with 4 samples.

How the data were processed

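Single-cell RNA sequencing was measured with 10x Genomics 3' chemistry on living (DAPI-negative) CD45-positive kidney leukocytes of mice with nephrotoxic nephritis, an experimental glomerulonephritis induced by antibodies against the kidney, harvested on day 10. The labels put 2 libraries in the BTLA knockout group (BTLA-KO) and 2 in the wild-type group (WT), and the series design calls them biological replicates. The cells were enriched on magnetic columns and sorted by flow cytometry. Library, not cell, was the unit of replication in the tests of genes and of class shares.

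The deposited per-library tables hold UMI counts of 32285 genes per cell barcode, as whole numbers without normalization. A deposited combined table holds the counts of the cells the authors kept, and 2 deposited annotation tables give the authors' cell class and cluster of each cell, for all leukocytes and for T cells. The submitters' processing notes name Cell Ranger 6.1.2, Seurat 4.1.1 and the mm10 build, without a role or an order. For every kept cell the combined table was identical to the per-library tables (summed difference 0). The 4 per-library tables hold 23631 barcodes, of which 20233 were kept. All kept cells had more than 500 and at most 5000 detected genes and under 5% mitochondrial counts, and 315 further barcodes met these bounds without being kept. How the classes were assigned is not given in the sources used here beyond column names, and the deposited classes were used as they stand, under their deposited names. Markers fixed before the data were examined were used to describe them. The T cell annotation holds 3244 cells. A further 267 cells of the T class in the annotation of all leukocytes are not in it.

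The kept cells held 54830547 and 63564384 UMIs in the BTLA-KO replicates and 30223724 and 46713024 in the WT replicates. Replicates of a group were distinct libraries: a chi-square test of their summed counts gave 36.9 per degree of freedom for BTLA-KO and 15.6 for WT. Intervals of single-library levels are exact Poisson intervals at 95%, a count of 0 allows up to 3 counts, and both cover counting error only.

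UMI counts were summed per library over the cells of a class and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr at its defaults, TMM scaling, two-sided, Benjamini-Hochberg over the genes tested, threshold 0.05). The main comparisons were all leukocytes, T cells (the deposited T cell annotation) and mononuclear phagocytes, taken as the annotated macrophage or monocyte class with the most cells, which was the deposited class M1. Each other class with at least 20 cells in every library was tested alone. Granulocytes (fewest cells in a library 9), Kidney Cells (8), Cycling T Cells (9), Teff 3 (10) and Teff 4 (10) fell below that minimum and their genes were not tested. Levels are CPM, summed UMIs scaled to a common library total, with the SD over n = 2 libraries. Per-library levels of Btla and Tnfrsf14 use the plain total and group levels of other genes the TMM-scaled total. Fold changes are log2 of BTLA-KO over WT with the standard error (SE) of the fit. Class shares were tested with the edgeR quasi-likelihood test on the number of cells per class and library, offset by the annotated cells of the library, with Benjamini-Hochberg adjustment over classes. With 2 against 2 libraries an exact permutation test of shares cannot go below p = 0.333. The difference of the genotype effect between T cells and class M1 was tested as the class by genotype interaction over the 8 sums with library as a block.

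Lists of genes were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01, log2 CPM with prior count 2, at least 3 members tested, Benjamini-Hochberg over the lists of a class). T cell lists were tested in T and NK classes, myeloid lists in mononuclear phagocyte and dendritic classes, and both in all leukocytes. The T cell lists were the BTLA and HVEM pathway, Th1, Th17 and type 3, Th2 and type 2, regulatory T cell, follicular helper T, inhibitory receptor, cytotoxic, T cell receptor activation, and naive and central memory T genes. The myeloid lists were complement and scavenger genes of resident macrophages, classical monocyte genes, lipid-associated and profibrotic macrophage genes, and Fc gamma receptors. Lists used in every class were the type I interferon response, interferon gamma response, MHC class II presentation, inflammatory cytokines and NF-kB targets, cell cycle, glycolysis and hypoxia, and respiratory chain. Technical lists were dissociation stress, kidney tubule, erythrocyte, platelet, endothelial and stromal, immunoglobulin, sex-linked and mitochondrially encoded genes, and the chromosome 16 neighbours of Btla. A median over members is the median log2 fold change of the members tested. The groups, lists, markers, tests, the rule for named genes and the alternatives were fixed before the data were examined.

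The rule for named genes took, in the main comparisons, Btla and Tnfrsf14, and up to 10 genes each way with the largest absolute log2 fold change. These needed an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap of the groups, and variable, joining and diversity segments, sex-linked genes and predicted genes were left out. From each list described, 2 to 4 members with the smallest p were named, except a member that is not reported here. Where fewer than 5 genes passed, the 5 each way with the smallest p are given as values. Other classes took up to 3 genes each way and the interaction up to 5. Other genes are said to have been chosen after their values were seen.

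Gene positions come from GENCODE release M21 on mm10, which placed 14097 of the 14235 gene symbols tested in all leukocytes. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scanpy 1.11.5 and matplotlib 3.10.9.

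The gene test was tested on counts drawn from a negative binomial at the mean levels and gene-wise dispersions of these libraries, with changes added. Of genes changed by 1 on the log2 scale, it called 68.4% in all leukocytes, 62% in T cells and 70.8% in class M1, and of those changed by 2 it called 92.9%, 95.9% and 96.9%. Unchanged genes made up 23 of 179, 20 of 176 and 18 of 179 calls. Genes were drawn independently there, without deviations that many genes of a library share. In the edgeR test of the real class M1 sums, Btla at -2.83 (adjusted p = 0.0951) and Ccl1 at 2.76 (adjusted p = 0.548) did not pass. These rates therefore do not carry over to the real sums, and few calls do not show that few genes changed. In 100 simulations the share test called the T class, the only class raised (2-fold), in 92%, and 7% of sets without a change had a call. Shares there varied between libraries with an SD of 0.1 on the natural log scale. Some real classes varied more, such as M2 at 6.93% and 3.91% in the BTLA-KO libraries, so the rate does not carry over to them.

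The alternatives were DESeq2 size factors, library size alone, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, equal cell numbers per library, technical lists left out before scaling, and leaving out each library in turn. For shares they were TMM across classes, the most populous class left out, and exact permutation. For lists they were an estimated correlation, fry, a prior count of 0.5 and library size alone. With 2 libraries per group an estimated correlation and fry leave few residual degrees of freedom, so hardly any list could pass under them. A call lost under either therefore does not decide whether the list changed, and every list call rests on the preset correlation. With that preset the test sets members against other genes, so a small p does not measure how far the libraries of a group differ. Doublets were not removed by the authors as far as the sources used here say, and were kept. Scrublet with its own threshold called 3 of 20233 cells doublets, so leaving out called doublets was not run. Leaving out the 5% of cells with the highest doublet scores in each library, and leaving the deposited class Kidney Cells out of all leukocytes, were added after seeing the data. The labels give no batch or date, so batch and genotype cannot be told apart.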

Results

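Kidney leukocytes of mice lacking BTLA, an inhibitory receptor of lymphocytes, were compared with those of wild-type mice during nephrotoxic nephritis, in 2 libraries per genotype. The comparison asks how loss of BTLA changes the infiltrate of the inflamed kidney on day 10. The libraries held 5412 and 7361 kept cells in BTLA-KO and 2939 and 4521 in WT. Median UMIs per cell were 8334 and 7090 in BTLA-KO against 8660 and 8636 in WT, and median detected genes were 2334 and 2125 against 2329 and 2403. The median mitochondrial share of a cell's UMIs was 0.928% and 1.46% in BTLA-KO against 0.541% and 0.555% in WT. Sums over all leukocytes held 30223724 to 63564384 UMIs, those over class M1 23674938 to 47779600 and those over T cells 2045101 to 7118838.

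Marker levels described the deposited classes. Class M1 carried macrophage markers at a median of 551 CPM, classical monocyte markers at 214 CPM and those of type 2 conventional dendritic cells at 140 CPM. Class M2 was led by neutrophil markers (1308 CPM), with classical monocyte markers at 327 CPM and macrophage markers at 298 CPM. DC was led by markers of type 1 conventional dendritic cells (470 CPM), Granulocytes by mast cell and basophil markers (351 CPM) and Kidney Cells by tubule markers (706 CPM). NK/NKT carried NK cell and ILC1 markers at 685 CPM and T cell markers at 111 CPM. Among T cells, Teff 2 carried T cell markers at 595 CPM beside gamma delta T cell markers at 411 CPM. Teff 3 carried markers of type 2 innate lymphoid cells at 384 CPM, with T cell markers at 22.2 CPM. Regulatory T cell markers stood at 305 CPM in Tregs, which also carried T cell markers at 805 CPM and markers of type 2 innate lymphoid cells at 128 CPM. CD8 T cell markers stood at 853 CPM in Cd8+ T.

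Btla transcripts were lower in BTLA-KO in each of the 7 sets of cells, all leukocytes included, in which they could be tested, with log2 fold changes of -3.06 to -1.73. These sets share cells and are not independent. Btla (ENSMUSG00000052013.15, mm10 chromosome 16, 45224315 to 45257670, plus strand) gave 117 and 150 UMIs in the BTLA-KO libraries and 459 and 652 in the WT libraries. These are 2.13 CPM (95% Poisson interval 1.76 to 2.56) and 2.36 CPM (2.00 to 2.77) against 15.2 CPM (13.8 to 16.6) and 14.0 CPM (12.9 to 15.1). Btla fell in all leukocytes (log2 -2.73, SE 0.12, adjusted p = 0.0244), in B cells (-2.44, SE 0.29, adjusted p = 0.0205) and in DC (-3.06, SE 0.18, adjusted p = 0.000258). In T cells its log2 fold change was -1.73 (SE 0.28, adjusted p = 0.499), from 3.80 and 3.93 CPM against 11.7 and 13.2 CPM. In class M1 it was -2.83 (SE 0.16, adjusted p = 0.0951). Class M2 held 0 and 0 Btla UMIs in BTLA-KO, which allows up to 1.72 and 2.93 CPM, against 5 and 6 in WT. Among classes with enough cells but too few Btla counts to test, the groups overlapped in Cd8+ NKT, Cd8+ T and Tregs and in no other. Levels were 0 and 8.12 against 10.6 and 6.18 CPM in Cd8+ NKT, 1.59 and 0 against 0 and 8.73 CPM in Cd8+ T, and 9.21 and 6.63 against 0 and 22.0 CPM in Tregs. The all-leukocyte call was kept without BTLA-KO replicate 2 (adjusted p = 0.0274) and lost without BTLA-KO replicate 1 (0.109), WT replicate 1 (0.201) or WT replicate 2 (0.170), at log2 fold changes of -2.81 to -2.66. Btla in all leukocytes also lost its call with the replicate number as a block (-2.73, adjusted p = 0.208). Which part of Btla was deleted is not given in the sources used here, and 3' tags can lie outside it.

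Tnfrsf14 (ENSMUSG00000042333.16, mm10 chromosome 4, 154921933 to 154928563, minus strand), which encodes the BTLA ligand HVEM, was measured at 1.68 and 1.76 CPM in BTLA-KO and at 1.22 and 1.54 CPM in WT. Its log2 fold change was 0.27 in all leukocytes (SE 0.21, adjusted p = 0.671) and 0.42 in class M1 (adjusted p = 0.577), and neither passed. Tnfrsf14 had too few counts in T cells to be tested.

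**Figure D1:**
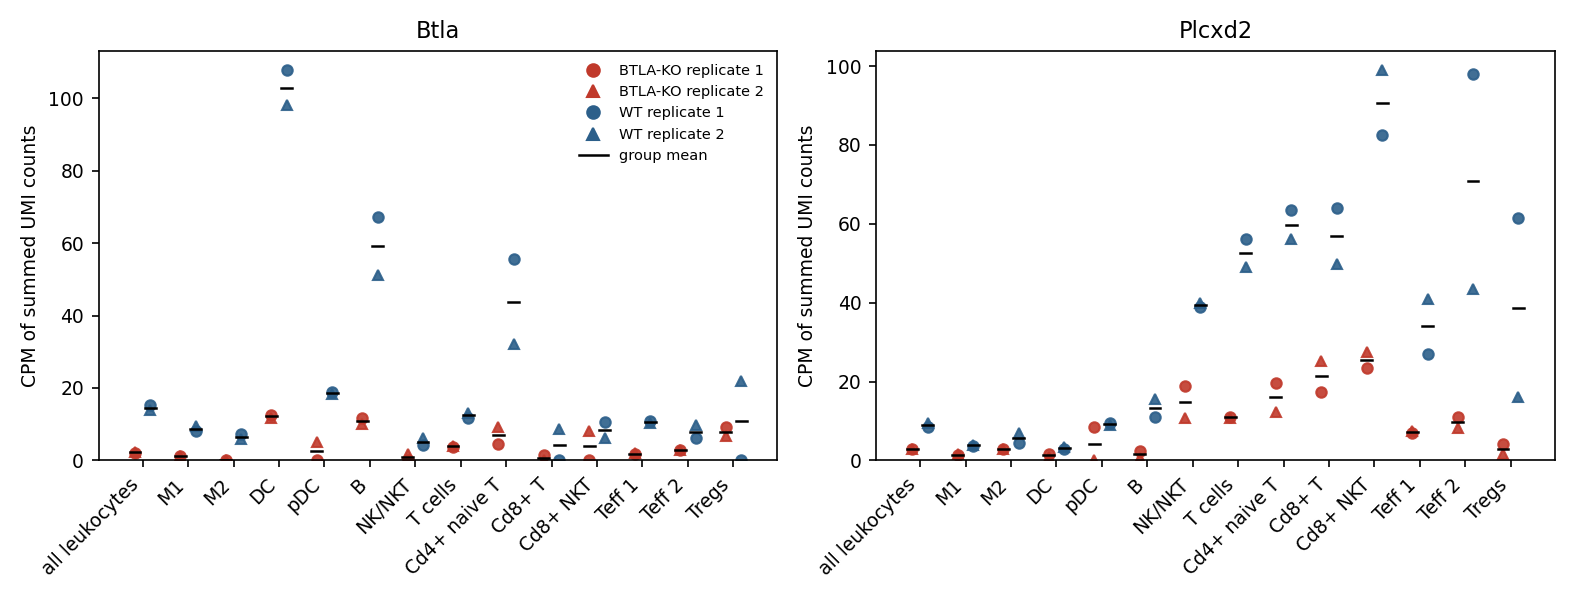
CPM of summed UMIs for Btla (left) and its chromosome 16 neighbour Plcxd2 (right) in all leukocytes and in 13 cell classes, with circles and triangles for replicates 1 and 2 (red BTLA-KO, blue WT) and black lines for group means. In all leukocytes Btla stands at 2.13 and 2.36 CPM in BTLA-KO against 15.2 and 14.0 CPM in WT.

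Cell class shares were compared to ask whether the make-up of the infiltrate differed between genotypes. T cells made up 18.9% ± 2.69 of kept cells in BTLA-KO and 14.1% ± 0.889 in WT (SD, n = 2), a log2 fold change of 0.42 (SE 0.15, adjusted p = 0.437). Class M1 took 63.2% ± 0.698 against 68.1% ± 0.682 (log2 -0.11, adjusted p = 0.533), with no overlap of the groups. Kidney Cells, the class with tubule markers, were 0.251% ± 0.145 in BTLA-KO against 1.01% ± 0.683 in WT (log2 -1.91, adjusted p = 0.437). Shares of class M2 were 5.42% ± 2.13 against 4.04% ± 0.112 (log2 0.42, adjusted p = 0.571, and -0.04 without BTLA-KO replicate 1). B cells made up 3.71% against 3.37% (adjusted p = 0.533), NK/NKT 5.29% against 5.89% (0.733) and DC 2.26% against 2.43% (0.911). Plasmacytoid dendritic cells were 0.686% against 0.705% (0.973) and Granulocytes 0.342% against 0.374% (0.915). In edgeR 0 of 9 classes passed, 0 had an unadjusted p under 0.05, and an exact permutation test cannot go below p = 0.333 here. Leaving out 1 library turned the direction for DC (0.20 without WT replicate 1), NK/NKT (0.07 without WT replicate 2), Granulocytes (0.27 without BTLA-KO replicate 1, 0.19 without WT replicate 2) and plasmacytoid dendritic cells (0.44 and 0.03 without these).

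Within T cells, regulatory T cells made up more of the BTLA-KO cells and Cd8+ T cells fewer, and neither passed. Tregs were 18.5% ± 5.45 of annotated T cells in BTLA-KO against 11.8% ± 1.95 in WT (SD, n = 2), a log2 fold change of 0.63 (SE 0.31, adjusted p = 0.240). Cd8+ T cells were 14.5% ± 0.533 against 22.8% ± 3.27 (log2 -0.66, SE 0.30, adjusted p = 0.240). Teff 3, the class with markers of type 2 innate lymphoid cells, made up 4.61% ± 1.03 against 2.84% ± 0.158 (log2 0.70, adjusted p = 0.271). Cd8+ NKT were 11.8% ± 0.394 against 14.9% ± 3.23 (log2 -0.32), Teff 1 20.6% ± 7.68 against 18.0% ± 5.47 (0.22), Teff 2 8.25% against 9.74% (-0.24) and Cycling T Cells 4.66% against 3.53% (0.33), at an adjusted p of 0.593 each. Cd4+ naive T cells were 13.9% against 13.2% and Teff 4 3.21% against 3.25% (adjusted p = 0.910 each). In edgeR 0 of 9 T cell classes passed, and 1, Cd8+ T, had an unadjusted p under 0.05 (p = 0.0383, exact permutation p = 0.333). Direction turned without BTLA-KO replicate 1 for Cd4+ naive T (-0.30) and Teff 4 (0.02), without BTLA-KO replicate 2 for Teff 1 (-0.22) and without WT replicate 2 for Teff 1 (-0.08) and Teff 4 (0.24). The permutation p of 0.333 for Tregs, Cd8+ T and Teff 3 was the smallest an exact test can give.

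**Figure D2:**
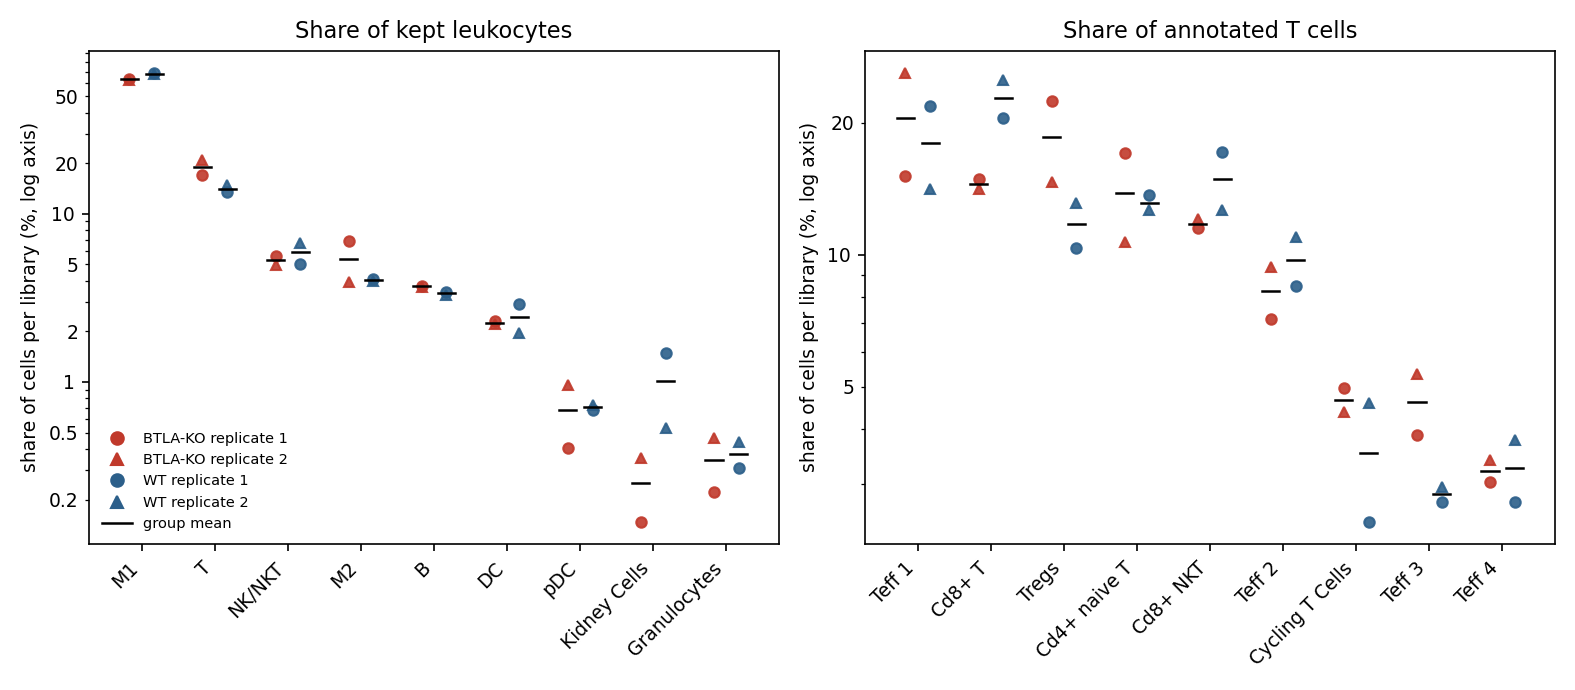
Share of cells per library (%, log axis) of each deposited class among kept leukocytes (left) and among annotated T cells (right), with circles and triangles for replicates 1 and 2 (red BTLA-KO, blue WT) and black lines for group means. Cd8+ T cells average 14.5% of T cells in BTLA-KO and 22.8% in WT, a difference that did not pass.

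In all leukocytes together, the genes higher in BTLA-KO with the smallest p were Ikzf2, which encodes a transcription factor of regulatory T cells, mt-Nd5, a mitochondrially encoded subunit of complex I, Izumo1r, a receptor on regulatory and anergic T cells, the chemokine gene Ccl1 and the adhesion molecule gene Vcam1. Lower were Btla, Plcxd2, a phospholipase C-like gene that lies 701.6 kb from Btla, Ifitm1, an interferon-induced antiviral gene, Hsph1, a heat shock protein gene, and B4galt4, a galactosyltransferase gene 6455 kb from Btla. Only Btla passed the test, and Hsph1 is also in the technical list of dissociation stress genes. Ikzf2 was measured at 29.8 ± 0.492 CPM in BTLA-KO and 17.7 ± 1.13 in WT (SD, n = 2, log2 0.75, SE 0.08), and Ccl1 at 39.4 ± 8.998 against 14.2 ± 2.76 (log2 1.46, SE 0.21). Log2 fold changes were 0.56 for mt-Nd5 (SE 0.06), 0.88 for Izumo1r (SE 0.10) and 0.62 for Vcam1 (SE 0.09). They were -1.65 for Plcxd2 (SE 0.13, adjusted p = 0.272), -0.87 for Ifitm1 (SE 0.08, adjusted p = 0.345), -0.72 for Hsph1 (SE 0.09) and -0.97 for B4galt4 (SE 0.14), with an adjusted p of 0.551 for those without a value of their own. Of 14235 genes tested, 1 passed, 1249 (8.77%) had an unadjusted p under 0.05, and 43.9% had no overlap of the groups, where chance gives 33.3%. DESeq2 called 41 genes. Leaving out BTLA-KO replicate 1, WT replicate 1 or WT replicate 2 left 0 calls, and leaving out BTLA-KO replicate 2 gave 4.

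Genes of regulatory T cells and of type 2 immunity were higher in BTLA-KO among all leukocytes, in all their measured members, and both calls were lost with an estimated correlation. Of the regulatory T cell genes, 15 of 15 were higher (median log2 0.77, adjusted p = 9.91e-08, adjusted p = 0.781 with an estimated correlation), 7 of them when adjusted over the list alone and 0 over all genes. They included Tnfrsf18 at 64.5 against 42.8 CPM (log2 0.59), Tnfrsf4, a costimulatory receptor gene, at 62.1 against 27.1 CPM (log2 1.19, SE 0.20) and Ikzf2. Of the Th2 and type 2 genes, 9 of 9 were higher (median 1.01, adjusted p = 7.01e-06, adjusted p = 0.781 with an estimated correlation), 6 when adjusted over the list alone. Il1rl1, the interleukin 33 receptor gene, stood at 17.3 against 8.08 CPM (log2 1.09, SE 0.21), Gata3, the type 2 transcription factor gene, at 34.5 against 19.1 CPM (log2 0.85, SE 0.18), and Il5, the eosinophil growth factor gene, had a log2 fold change of 3.33 (SE 0.71). Both lists kept their call with each library left out, with medians of 0.49 to 0.88 and 0.84 to 1.14. T cells also made up more of the BTLA-KO libraries (18.9% against 14.1%).

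Complement and scavenger genes of resident macrophages and inflammatory cytokine genes were higher in all leukocytes, at adjusted p = 0.781 with an estimated correlation for both. For the complement and scavenger list 14 of 14 members were higher (median log2 0.34, adjusted p = 0.00175, adjusted p = 0.781 with an estimated correlation), 0 adjusted over the list alone. Apoe, a lipid carrier gene, stood at 4305 against 2860 CPM (log2 0.59, SE 0.15), and log2 fold changes were 0.49 for the chemokine gene Pf4 and 0.87 for the mannose receptor gene Mrc1 (SE 0.28). Without WT replicate 2 the list median was 0.27 and its call was lost (adjusted p = 0.105). Of the inflammatory cytokines and NF-kB targets, 16 of 18 were higher (median 0.33, adjusted p = 0.0291, adjusted p = 0.781 with an estimated correlation), 0 adjusted over the list alone. Nfkbiz and Tnfaip3, both feedback regulators of NF-kB, had log2 fold changes of 0.34 and 0.61. The inflammatory list median was -0.01 without BTLA-KO replicate 1 (adjusted p = 0.679) and 0.15 without WT replicate 1 (0.461). T cell receptor activation genes were higher for 14 of 15 members (median 0.36, adjusted p = 0.0140, adjusted p = 0.781 with an estimated correlation), 2 adjusted over the list alone, with Egr3 at 0.36 (SE 0.07). The activation list lost its call without BTLA-KO replicate 1 (median 0.01) or WT replicate 1 (0.18).

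Type I interferon response genes were lower in BTLA-KO on average, a difference that rested on WT replicate 2. In all leukocytes 0 of 21 members were higher (median log2 -0.58, adjusted p = 0.00377, adjusted p = 0.781 with an estimated correlation), and 0 passed adjusted over the list alone. Oas1a, an antiviral RNA sensor gene, had -0.78, Xaf1 -0.56, Usp18, which removes ISG15, -0.81 and Ifi27l2a -0.77. The mean of the members was 5.35 and 5.18 on the log2(CPM + 1) scale in BTLA-KO and 5.12 and 6.26 in WT. Without WT replicate 2 the median was 0.17, and without BTLA-KO replicate 2 the call was lost (adjusted p = 0.0919). Cytotoxic genes were lower for 12 of 14 members (median -0.25, adjusted p = 0.0277, adjusted p = 0.781 with an estimated correlation), 1 of them, Klrd1 (-0.52, SE 0.09), adjusted over the list alone. The cytotoxic list had a median of -0.03 without WT replicate 2 (adjusted p = 0.939) and -0.16 without BTLA-KO replicate 1 (0.150). MHC class II genes were lower for 9 of 10 members (median -0.12, adjusted p = 0.0192), 0 adjusted over the list alone, with H2-Oa at -0.22. Their call was lost without BTLA-KO replicate 2 (median -0.05) or WT replicate 1 (-0.07), and adjusted p = 0.781 with an estimated correlation.

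Among technical lists in all leukocytes, mitochondrially encoded genes were higher in 13 of 13 members (median log2 0.50, adjusted p = 9.91e-08, adjusted p = 0.781 with an estimated correlation), 12 of them adjusted over the list alone. mt-Co1, a subunit of complex IV, stood at 2518 against 1733 CPM (log2 0.54) and mt-Nd4l had 0.45. The list held in each leave-out, at 0.29 to 0.64. Nuclear respiratory chain genes went the other way, lower for 16 of 18 members (median -0.13, adjusted p = 0.00101, adjusted p = 0.781 with an estimated correlation), 0 adjusted over the list alone, and lost their call without WT replicate 1 (adjusted p = 0.0811). Kidney tubule genes were lower for 17 of 17 members (median -1.48, adjusted p = 4.09e-05, adjusted p = 0.781 with an estimated correlation), 2 adjusted over the list alone. Lrp2, the proximal tubule receptor megalin, stood at 0.242 against 1.79 CPM. The tubule median was -0.33 without WT replicate 1, the library with the most Kidney Cells, and the call was lost (adjusted p = 0.157). Cell cycle genes were lower for 18 of 20 members (median -0.12, adjusted p = 0.0277), 0 adjusted over the list alone, with a median of 0.05 without BTLA-KO replicate 1. Their call was also lost without WT replicate 1 (-0.16) and WT replicate 2 (-0.08), and adjusted p = 0.786 with an estimated correlation.

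The other 18 lists did not pass in all leukocytes. Medians were 0.19 for naive and central memory T genes (8 of 10 higher, adjusted p = 0.0609), 0.24 for inhibitory receptors (9 of 11, 0.0666) and 0.25 for Th17 and type 3 genes (9 of 14, 0.0841). They were -0.12 for classical monocyte genes (4 of 13, 0.108), -0.08 for glycolysis and hypoxia (6 of 18, 0.144), 0.18 for lipid-associated and profibrotic macrophage genes (14 of 18, 0.144) and 0.22 for follicular helper T genes (6 of 8, 0.144). Endothelial and stromal genes had -0.47 (2 of 9 higher, 0.167), the BTLA and HVEM pathway -0.02 (4 of 9, 0.181), in which Btla passed, the interferon gamma response -0.08 (8 of 22, 0.215) and erythrocyte genes 1.32 (2 of 3, 0.512). Th1 genes had 0.04 (8 of 14, 0.645), sex-linked genes 0.07 (3 of 4, 0.697), dissociation stress genes 0.16 (13 of 20, 0.732) and platelet genes 0.07 (2 of 3, 0.732). Fc gamma receptors had a median of 0.05 (3 of 6, 0.773) while the test pointed down, and immunoglobulin genes a median of -0.05, a mean of 0.28 and a test pointing down (5 of 10, 0.942). Adjusted over the list alone, 2 inhibitory receptors and 2 naive T genes were higher, 2 dissociation stress genes and Btla were lower, and the rest of these 18 lists, the chromosome 16 neighbours apart, had 0. For the chromosome 16 neighbours of Btla the median was -0.01 (9 of 22 higher, adjusted p = 0.201), and 3 genes, Plcxd2, Slc35a5 and Phldb2, were lower when adjusted over the list alone.

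**Figure D3:**
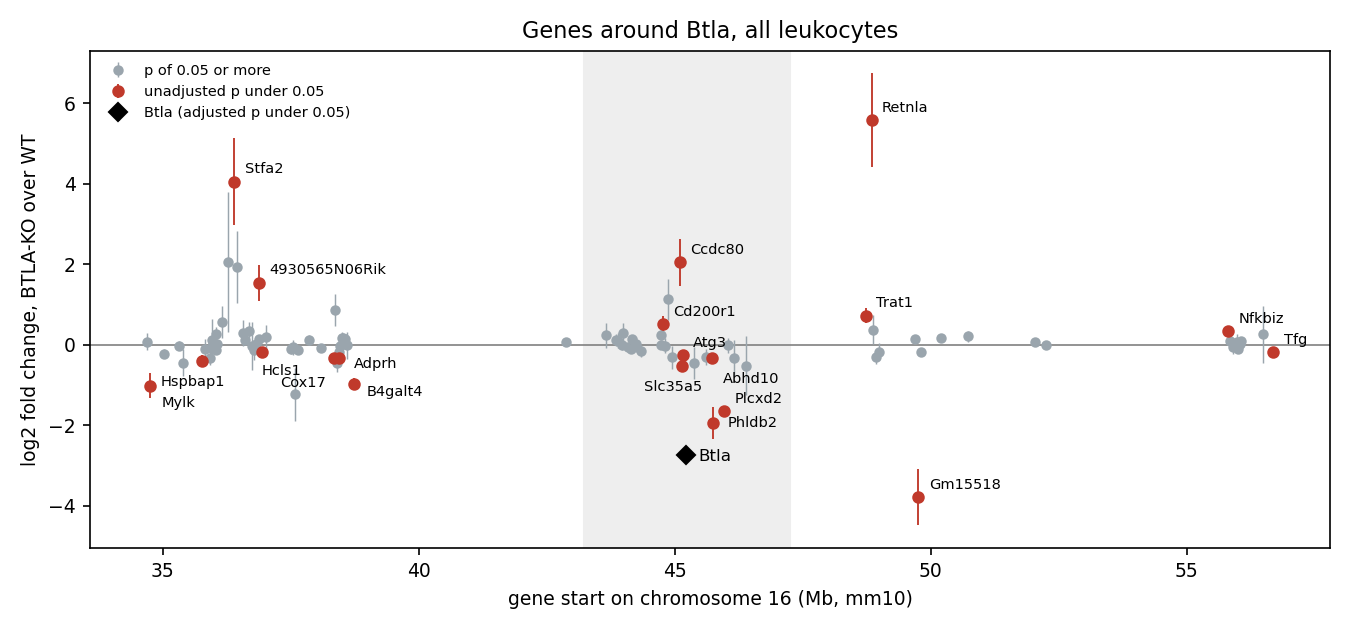
Log2 fold change (BTLA-KO over WT, bars SE) in all leukocytes of the genes tested around Btla, by gene start on chromosome 16 (Mb, mm10). Red points have an unadjusted p under 0.05, grey points do not, the diamond is Btla at -2.73, and the grey band marks 2 Mb on either side.

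Within T cells the question was whether loss of the receptor changes their transcripts. Plcxd2 (ENSMUSG00000087141.1, mm10 chromosome 16, 45959263 to 46010218, minus strand) was the gene that passed, at 10.8 ± 0.226 CPM in BTLA-KO and 53.7 ± 5.90 CPM in WT (SD, n = 2). Plcxd2 fell by 2.30 on the log2 scale (SE 0.16, adjusted p = 0.00319). As groups, cytotoxic genes were lower (adjusted p = 0.656 with an estimated correlation), while type 2, regulatory T cell and cell cycle genes were higher (adjusted p = 0.738 with an estimated correlation). The cell cycle median was -0.04 without WT replicate 1. Of 10351 genes tested 1 passed, 596 (5.76%) had an unadjusted p under 0.05 and 36.1% had no overlap of the groups, where chance gives 33.3%. DESeq2 called 2. The count was 39 without BTLA-KO replicate 1, 45 without BTLA-KO replicate 2, 1 (Ccl1) without WT replicate 1 and 0 without WT replicate 2. Plcxd2 stood at -2.32 and -2.27 without a BTLA-KO replicate (adjusted p = 0.000125 and 0.00162). It stood at -2.20 without WT replicate 1 (0.1001) and at -2.41 without WT replicate 2 (0.189).

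Genes that did not pass in T cells are given as values. Higher with the smallest p were Hes1, a Notch target gene, at 30.6 against 10.4 CPM (log2 1.64, SE 0.29, adjusted p = 0.515), Gata3 at 227 ± 32.3 against 147 ± 4.48 CPM (log2 0.63, SE 0.12), Hs3st1, a sulfotransferase gene, at 1.01 (SE 0.19), Ncmap at 2.20 and the predicted gene Gm20186 at 0.69 (adjusted p = 0.367). Lower were Cd8b1, the CD8 beta chain gene, at 235 ± 17.8 against 404 ± 39.0 CPM (log2 -0.79, SE 0.10, adjusted p = 0.259), Hsph1 at -0.76 (SE 0.13, adjusted p = 0.515) and Btla. Csta2, a stefin gene with near-identical copies, had 0 and 0 UMIs in BTLA-KO against 6 and 11 in WT.

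Cytotoxic genes were lower in BTLA-KO T cells, and type 2 and regulatory T cell genes higher, with each library left out in turn, and none of the calls held with an estimated correlation. Of the cytotoxic genes 12 of 14 were lower (median log2 -0.47, adjusted p = 1.19e-06, adjusted p = 0.656 with an estimated correlation), 9 of them adjusted over the list alone and 0 over all genes. The chemokine gene Ccl5 stood at 3377 against 6075 CPM (log2 -0.85, SE 0.17), the NKG2D receptor gene Klrk1 at 133 against 207 CPM (-0.64, SE 0.13), Gzmm, a granzyme gene, at 10.03 against 19.98 CPM (-0.97, SE 0.21) and Klrc1 at -0.61 (SE 0.12). Of the Th2 and type 2 genes 9 of 9 were higher (median 0.78, adjusted p = 1.29e-06, adjusted p = 0.738 with an estimated correlation), 6 adjusted over the list alone. Il1rl1 stood at 57.6 against 25.2 CPM (log2 1.16, SE 0.25), the repair factor gene Areg at 263 against 151 CPM (0.78, SE 0.21), and Il5 had 2.69 (SE 0.84). Of the regulatory T cell genes 13 of 14 were higher (median 0.57, adjusted p = 7.55e-05, adjusted p = 0.738 with an estimated correlation), 2 adjusted over the list alone. Ikzf2 stood at 164 against 107 CPM (log2 0.63, SE 0.13), Tnfrsf4 at 431 against 218 CPM (0.99, SE 0.23), and the checkpoint receptor gene Ctla4 had 0.53 (SE 0.17). Medians with each library left out were -0.49 to -0.41, 0.48 to 0.99 and 0.27 to 0.74. The shares of Cd8+ T, Teff 3 and Tregs among T cells, classes in which such genes are typically expressed, were 14.5% against 22.8%, 4.61% against 2.84% and 18.5% against 11.8%.

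Other T cell lists passed with a lower margin. Cell cycle genes were higher for 20 of 20 members (median log2 0.24, adjusted p = 0.000148, adjusted p = 0.738 with an estimated correlation), 0 adjusted over the list alone. Mki67, a proliferation marker gene, had 0.60 (SE 0.23), and without WT replicate 1 the list median was -0.04 (adjusted p = 0.817). The mitochondrially encoded genes were higher for 12 of 13 members (median 0.33, adjusted p = 0.000148, adjusted p = 0.738 with an estimated correlation), 7 adjusted over the list alone, with mt-Co1 at 0.39, and their call was lost without BTLA-KO replicate 2 (median 0.18). T cell receptor activation genes were higher for 12 of 15 (median 0.20, adjusted p = 0.0214, adjusted p = 0.738 with an estimated correlation), 1 adjusted over the list alone, with Il2ra, the interleukin 2 receptor alpha gene, at 0.90. The activation list lost its call without BTLA-KO replicate 1 (median 0.10) or WT replicate 1 (0.04). In the BTLA and HVEM pathway 6 of 8 were lower (median -0.28, adjusted p = 0.00713, adjusted p = 0.738 with an estimated correlation), 1 (Btla) adjusted over the list alone, with Ptpn6, the phosphatase SHP-1, at -0.31. Btla, the knocked-out gene, is itself a member and the list was not tested without it. The call therefore does not show a change of the rest of the pathway. The pathway lost its call without BTLA-KO replicate 1 (median -0.11).

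Interferon and Th1 genes were lower on average in BTLA-KO T cells, and their calls depended on the libraries used and were lost with an estimated correlation. The type I interferon response was lower for 18 of 20 members (median log2 -0.46, adjusted p = 0.0103, adjusted p = 0.740 with an estimated correlation), 0 adjusted over the list alone, with the antiviral RNA sensor gene Oas3 at -0.79 and Ifit3 at -0.83. Without WT replicate 2 its median was 0.07, and without BTLA-KO replicate 1 its call was lost (median -0.37). The interferon gamma response was lower for 20 of 22 (median -0.17, adjusted p = 0.0103, adjusted p = 0.738 with an estimated correlation), 0 adjusted over the list alone, with the GTPase gene Gbp4 at -0.43, and its call was lost without WT replicate 2 (median -0.07). Th1 genes were lower for 12 of 14 (median -0.23, adjusted p = 0.0126, adjusted p = 0.738 with an estimated correlation), 3 lower and 1 higher adjusted over the list alone. Nkg7, a cytotoxic granule gene that is also in the cytotoxic list, had -0.49 (SE 0.12), Stat4 -0.34 and the cytokine gene Il2 1.44 (SE 0.42). The Th1 call was lost without BTLA-KO replicate 1 (median -0.11) or WT replicate 2 (-0.09). Kidney tubule transcripts were lower for 3 of 3 members (median -0.99, adjusted p = 0.0164, adjusted p = 0.738 with an estimated correlation), 0 adjusted over the list alone. Their call was lost without BTLA-KO replicate 1 (median -0.49) or WT replicate 1 (-0.63).

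Medians of lists that did not pass in T cells were: glycolysis and hypoxia 0.03, dissociation stress -0.07 (3 lower adjusted over the list alone), naive and central memory -0.04 (1 lower adjusted over the list alone), MHC class II -0.23, inflammatory cytokines 0.09, follicular helper 0.17, sex-linked genes -0.02 and respiratory chain 0.00. Their adjusted p values were 0.157 to 0.939. Immunoglobulin genes had a median of 1.21 (adjusted p = 0.297). Inhibitory receptors had a median of -0.11 and a mean of 0.03, with the test pointing up (adjusted p = 0.887), and Cd5 was higher adjusted over the list alone (log2 0.46). Th17 and type 3 genes had a median of 0.06 and a mean of -0.10, with the test pointing up (adjusted p = 0.463). The chromosome 16 neighbours had a median of 0.01 and a mean of -0.10, with the test pointing down (adjusted p = 0.297), and Plcxd2 passed among them.

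**Figure D4:**
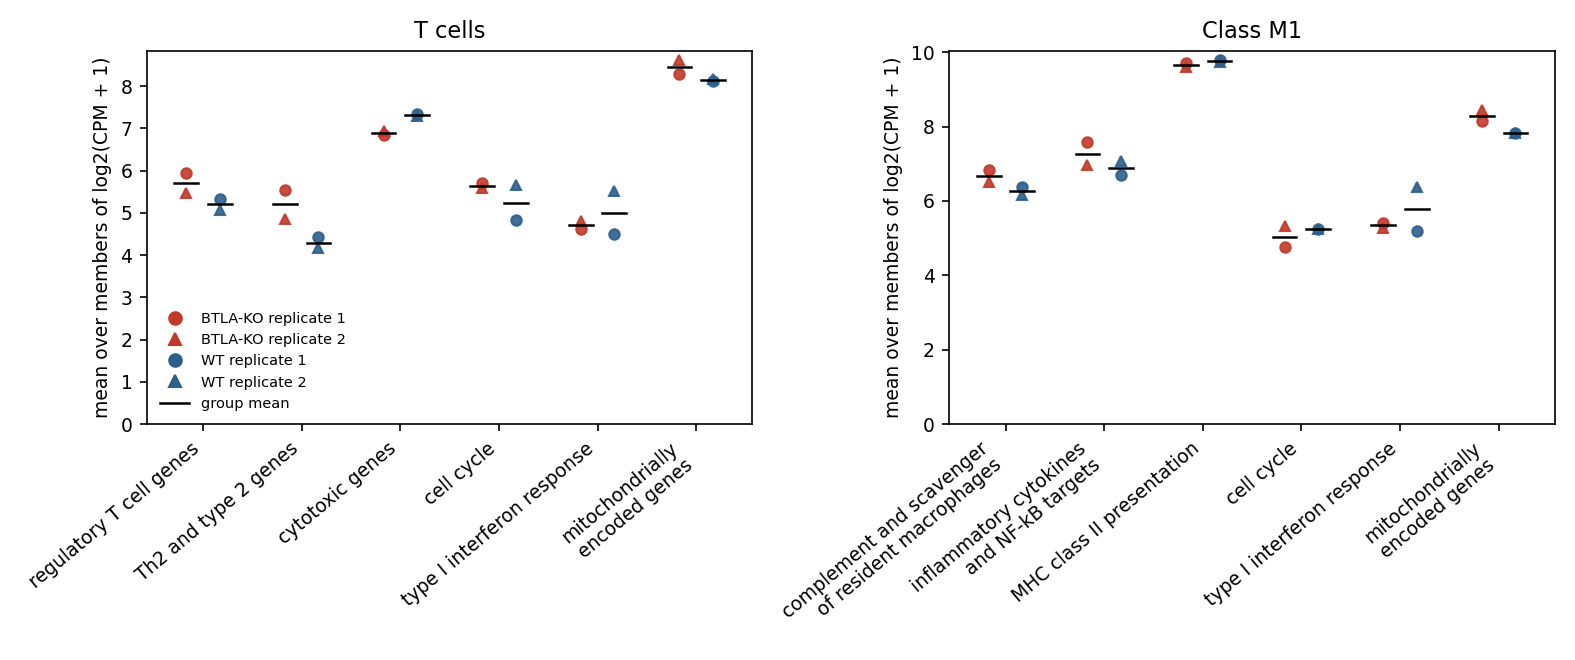
Mean over list members of log2(CPM + 1) per library in T cells (left) and class M1 (right), with circles and triangles for replicates 1 and 2 (red BTLA-KO, blue WT) and black lines for group means. In T cells the cytotoxic genes lie lower in both BTLA-KO libraries, while for the type I interferon response WT replicate 2 lies apart from the other 3 libraries.

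In mononuclear phagocytes (class M1) the comparison asked whether macrophages and monocytes, most of the kept cells, differed between genotypes. Macrophage complement and scavenger genes and inflammatory genes were higher in BTLA-KO as groups (adjusted p = 0.822 with an estimated correlation for both), and no gene passed on its own. The inflammatory median was 0.04 without BTLA-KO replicate 1. Higher with the smallest p were Vcam1 at 37.8 against 23.5 CPM (log2 0.69, SE 0.08), mt-Nd5 at 96.5 against 64.4 CPM (0.58, SE 0.07), Ccl1 at 6.35 against 0.903 CPM (2.76, SE 0.35) and the tetraspanin gene Tspan4 (0.67), with an adjusted p of 0.548 each. Gzmc, a granzyme gene, stood at 3.08 against 0.558 CPM (log2 2.45, adjusted p = 0.365, and -0.60 without the cells with the highest doublet scores). Lower were Ifitm1 at 159 ± 1.60 against 304 ± 15.5 CPM (SD, n = 2, log2 -0.93, SE 0.07, adjusted p = 0.195), Btla (-2.83, 0.0951), Ly6d (-1.50, SE 0.18), Plcxd2 (-1.41) and Hsph1 (-0.76), the last 3 at an adjusted p of 0.548. Of 13226 genes edgeR called 0, 1185 (8.96%) had an unadjusted p under 0.05, and DESeq2 called 21. The groups did not overlap for 43.9% of genes, where chance gives 33.3%. The count was 3 without BTLA-KO replicate 1, 157 without BTLA-KO replicate 2 and 0 without WT replicate 1 or WT replicate 2.

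Complement and scavenger genes were higher for 13 of 14 members in class M1 (median log2 0.41, adjusted p = 0.000298, adjusted p = 0.822 with an estimated correlation), 0 adjusted over the list alone. Apoe stood at 5423 against 3450 CPM (log2 0.65, SE 0.15), Mrc1 at 203 against 106 CPM (0.93, SE 0.27), and log2 fold changes were 0.54 for Pf4 (SE 0.15) and 0.24 for the complement gene C1qa. The complement list held without each library, at 0.26 to 0.58. Inflammatory cytokines and NF-kB targets were higher for 18 of 18 (median 0.44, adjusted p = 0.00388, adjusted p = 0.822 with an estimated correlation), 0 adjusted over the list alone. Nfkbiz stood at 383 against 296 CPM (log2 0.37, SE 0.08), Tnfaip3 had 0.64, Tnf 0.32 and the chemokine gene Cxcl1 0.52. The inflammatory median was 0.04 without BTLA-KO replicate 1 (adjusted p = 0.717) and 0.27 without WT replicate 1 (0.111). Lipid-associated and profibrotic macrophage genes were higher for 14 of 18 (median 0.23, adjusted p = 0.0165, adjusted p = 0.822 with an estimated correlation), 0 adjusted over the list alone. Trem2, a lipid-sensing receptor gene, stood at 136 against 89.2 CPM (log2 0.60, SE 0.15), Cd63 had 0.82 and the matrix gene Fn1 0.72. The lipid-associated list lost its call without BTLA-KO replicate 1 (adjusted p = 0.340) or WT replicate 2 (0.0851).

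The type I interferon response was lower for 21 of 21 members in class M1 (median log2 -0.64, adjusted p = 0.00185, adjusted p = 0.822 with an estimated correlation), 0 adjusted over the list alone, with Oas1a at -0.74 and Ifi27l2a at -0.80. Without WT replicate 2 the median was 0.15 and the list passed upward (adjusted p = 0.0409). Without BTLA-KO replicate 2 the interferon call was lost (adjusted p = 0.0860). Cell cycle genes were lower for 19 of 20 (median -0.19, adjusted p = 0.00364, adjusted p = 0.822 with an estimated correlation), 0 adjusted over the list alone, with the replication gene Mcm6 at -0.41, and their median was 0.08 without BTLA-KO replicate 1. MHC class II genes were lower for 9 of 10 (median -0.06, adjusted p = 0.0424, adjusted p = 0.822 with an estimated correlation), 2 adjusted over the list alone, H2-Oa (-0.30) and H2-Ob (-0.37), both of the mouse counterpart of the peptide-loading regulator HLA-DO. Their call was lost without BTLA-KO replicate 2 (median -0.01) or WT replicate 1 (-0.05). Among the deposited clusters of class M1, tested after seeing the files, the MHC class II median was -0.33 in cluster 2 (adjusted p = 1.29e-06, adjusted p = 0.650 with an estimated correlation), -0.11 in cluster 3 (0.0275, adjusted p = 0.805 with an estimated correlation), -0.18 in cluster 6 (0.0419, adjusted p = 0.786 with an estimated correlation) and -0.03 in cluster 0 (0.373).

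Mitochondrially encoded genes were higher for 13 of 13 members in class M1 (median log2 0.50, adjusted p = 6.65e-08, adjusted p = 0.822 with an estimated correlation), 11 adjusted over the list alone, and held without each library. Nuclear respiratory chain genes were lower for 16 of 18 (median -0.12, adjusted p = 0.00185, adjusted p = 0.822 with an estimated correlation), 0 adjusted over the list alone, and lost their call without BTLA-KO replicate 2 (median -0.07) or WT replicate 1 (-0.09). Kidney tubule transcripts were lower for 12 of 13 (median -0.74, adjusted p = 0.000298, adjusted p = 0.822 with an estimated correlation), 0 adjusted over the list alone, and lost their call without BTLA-KO replicate 1 (median -0.34). Lists that did not pass had medians of -0.08 (glycolysis and hypoxia), -0.06 (classical monocyte genes), -0.06 (interferon gamma response), 0.18 (dissociation stress), -0.43 (immunoglobulin), 0.08 (sex-linked) and 0.12 (Fc gamma receptors). The chromosome 16 neighbours had a median of -0.05 and a mean of 0.01, with the test pointing down, and endothelial and stromal genes a median of -0.02 with the test pointing up. Their adjusted p values were 0.0856 to 0.718, and adjusted over the list alone 2 chromosome 16 neighbours were lower, and 1 higher and 2 lower in each of the dissociation stress and immunoglobulin lists.

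**Figure D5:**
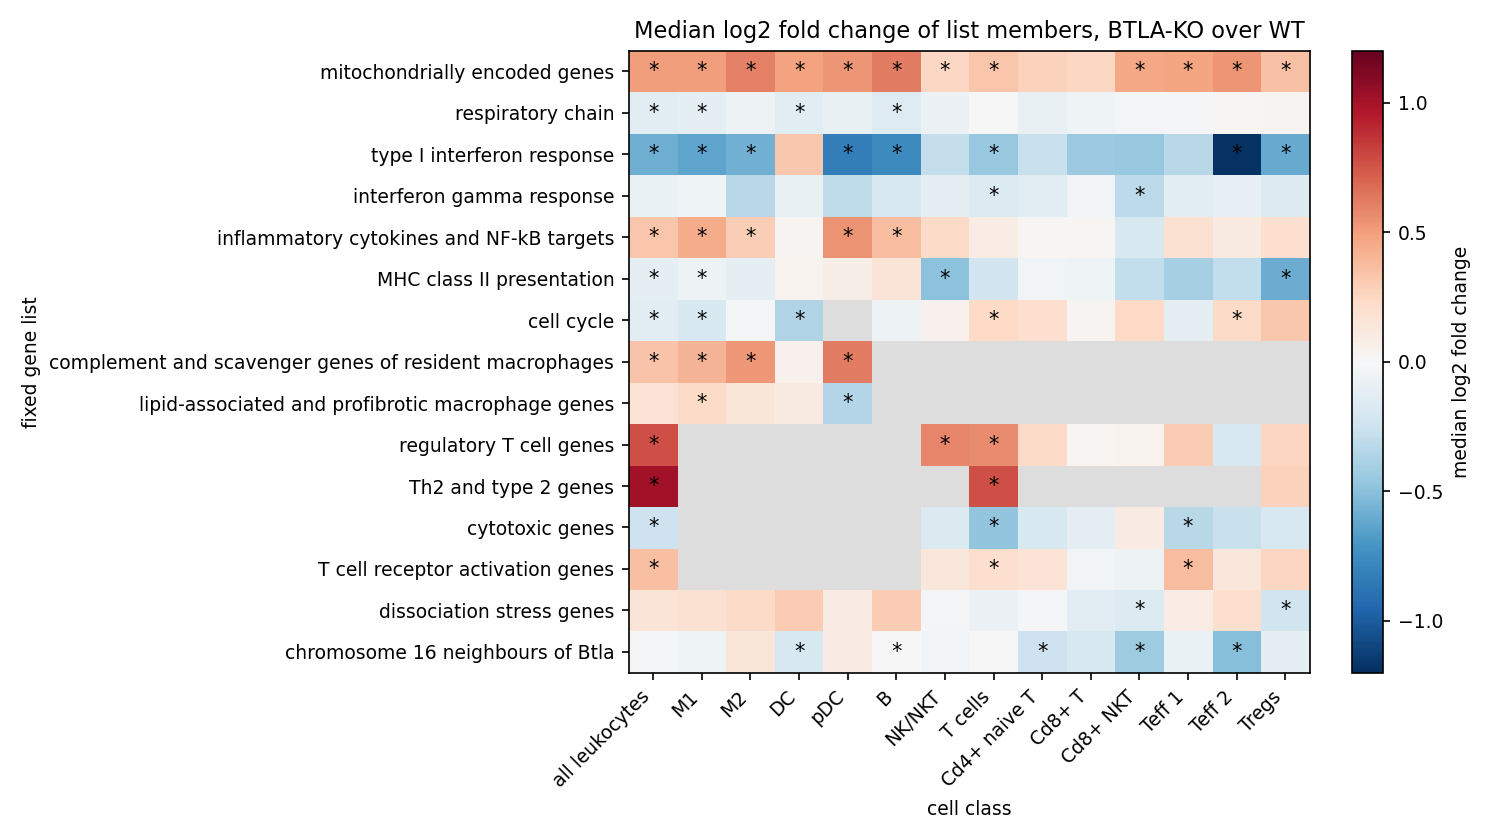
Median log2 fold change (BTLA-KO over WT, colour) of 15 fixed gene lists, listed by name, in all leukocytes and 13 cell classes, where stars mark an adjusted p under 0.05 in camera with the preset correlation, none of which held with an estimated correlation, and grey marks lists not tested. With 2 libraries per group an estimated correlation could pass hardly any list. Mitochondrially encoded genes have a positive median in each class shown, at 0.50 in all leukocytes.

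Other classes were tested alone, and few genes passed. In B cells 8 of 7963 genes passed, 1 higher and 7 lower. Leaving out each library in turn kept these calls but called many more genes, so this says little about how well they hold. Scaling by library size alone kept 3 of the 8 (Btla, mt-Co1 and Ms4a4b), the DESeq2 Wald test 4 and equal cell numbers per library 5. Cd200, which encodes an inhibitory ligand and lies 124.5 kb from Btla, fell from 50.1 to 7.30 CPM (log2 -2.75, SE 0.43, adjusted p = 0.0447), beside Btla. mt-Co1 rose from 2092 ± 27.8 to 3571 ± 196 CPM (SD, n = 2, log2 0.77, SE 0.11, adjusted p = 0.0447). Nkg7, Ms4a4b, Trbc2, Trac and Cd209a, transcripts of T, NK and dendritic cells partly named after their values were seen, also fell, Nkg7 from 115 to 28.4 CPM (log2 -1.99). Without the cells with the highest doublet scores 0 B cell genes passed, at log2 ratios of -2.60 for Cd200, -2.54 for Btla, -2.77 for Nkg7 and -0.61 for Cd209a. The Nkg7 value rests on WT replicate 2, at 134 CPM against 17.3 CPM in WT replicate 1 and 12.9 and 9.36 CPM in BTLA-KO. The B cell count was 76 and 112 without BTLA-KO replicates 1 and 2, and 97 and 114 without WT replicates 1 and 2. In pDC, Cd200 fell by 2.86 on the log2 scale (SE 0.41, adjusted p = 0.0136) and was the 1 of 3868 genes that passed, a call lost without BTLA-KO replicate 2, without the cells with the highest doublet scores, with library size alone and with equal cell numbers. The pDC count was 18 and 9 without the BTLA-KO replicates, and 58 and 26 without the WT replicates.

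In DC, 3 of 8719 genes passed: Btla, and the neutrophil alarmin genes S100a8 and S100a9, which rose. These genes were also called without each library in turn, but in fits that called more genes. S100a8 stood at 152 and 62.3 CPM in BTLA-KO against 4.18 and 4.601 in WT (log2 4.58, SE 0.53, adjusted p = 0.0303), and S100a9 at 227 and 101 against 10.8 and 5.75 (4.30, SE 0.46, adjusted p = 0.0250). The S100a8 UMIs came from few cells: 389 and 190 UMIs from 14 of 125 and 10 of 162 DC in BTLA-KO, and 7 and 8 UMIs from 6 of 85 and 7 of 89 DC in WT. Without the cells with the highest doublet scores S100a8 stood at 158 and 1.94 CPM and S100a9 at 236 and 5.04 CPM in BTLA-KO replicates 1 and 2, with log2 ratios of 4.15 and 3.96 that rest on replicate 1, and both calls were lost, with 1 gene passing. The DC count was 100 and 208 without BTLA-KO replicates 1 and 2, and 11 and 16 without WT replicates 1 and 2. In class M2, led by neutrophil markers, 5 of 6838 passed. The acute phase gene Saa3 (log2 3.78, SE 0.43, adjusted p = 0.00351), with 73 and 41 UMIs from 4 of 375 and 4 of 288 BTLA-KO cells against 1 and 4 UMIs from 1 of 121 and 3 of 179 WT cells, and Cstdc5, a stefin gene with near-identical copies (2.76, SE 0.30, 0.00351), rose. Klrd1 (-2.87, SE 0.41, 0.0192), the fatty acid carrier gene Fabp4 (-1.96, SE 0.25, 0.00816) and the corepressor gene Cbfa2t3 (-1.36, SE 0.22, 0.0462) fell. Without the cells with the highest doublet scores Saa3 and Cstdc5 passed and the 3 lower calls were lost, at log2 ratios of -1.22 for Klrd1, -1.94 for Fabp4 and -1.45 for Cbfa2t3. Of the 5 M2 calls, 4 were kept by the DESeq2 Wald test, 3 with equal cell numbers and 2 without BTLA-KO replicate 2. The M2 count was 29 without BTLA-KO replicate 1, 4 without BTLA-KO replicate 2, with 2 of the 5 genes kept, and 77 and 66 without the WT replicates.

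In T and NK classes the calls were few. In Cd8+ NKT, 2 of 5692 genes fell: Cxcl10, an interferon-induced chemokine gene (14.7 and 14.5 against 108 and 77.4 CPM, log2 -2.63, SE 0.32, adjusted p = 0.0111), and Plcxd2 (-1.83, SE 0.27, 0.0358). Both were also called without each library in turn, but in fits that called more genes. In Cd8+ T, 2 of 6250 fell, the GTPase regulator gene Arhgap31 (-2.71, SE 0.40, 0.0156), which lies 6511 kb from Btla, and the nuclear noncoding RNA gene Malat1 (-0.31, SE 0.04, 0.0156), and 0 passed without BTLA-KO replicate 2. In Teff 1, 1 of 5242 fell, the antiviral gene Ifitm3 (61.6 against 179 CPM, log2 -1.59, SE 0.22, adjusted p = 0.000737), and 0 passed without either BTLA-KO replicate. In NK/NKT 1 of 8433 passed, the predicted gene Gm15518, 4501 kb from Btla, outside the rule for named genes and named after its values were seen, with 0 UMIs in both BTLA-KO libraries against 14.1 and 18.2 CPM in WT and a call lost without WT replicate 2. With equal cell numbers per library 0 genes passed in Cd8+ NKT, Cd8+ T, Teff 1 and NK/NKT, and the DESeq2 Wald test kept Cxcl10 alone in Cd8+ NKT and 0 calls in the others. In the T class of the annotation of all leukocytes, which largely holds the same cells, 1 of 10549 passed, Plcxd2 (-2.31, adjusted p = 0.00169). edgeR called 0 of 5252 genes in Cd4+ naive T (247 with an unadjusted p under 0.05), 0 of 4785 in Teff 2 (212) and 0 of 6894 in Tregs (355), and DESeq2 called 0 in each. Left-out counts, in the order BTLA-KO replicates 1 and 2 then WT replicates 1 and 2, were 28, 15, 17 and 22 in Cd8+ NKT, 37, 0, 35 and 34 in Cd8+ T, 0, 0, 20 and 10 in Teff 1, and 15, 19, 28 and 40 in NK/NKT. In the same order they were 13, 10, 5 and 3 in Cd4+ naive T, 18, 16, 28 and 27 in Teff 2, 27, 25, 0 and 0 in Tregs, and 110, 254, 6 and 8 in the T class.

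Across all leukocytes and the classes, Plcxd2 was lower in BTLA-KO in 12 of 12 sets of cells tested (log2 -3.38 to -1.37), each with an unadjusted p under 0.05. The chaperone genes Hspa8 and Hsph1, the antiviral gene Ifitm3, Arhgap31 and Cd200 were chosen for this count after their values were seen. Hspa8 was lower in 15 of 15 (-0.48 to -0.22) and Hsph1 in 15 of 15 (-2.03 to -0.09). Both are members of the technical list of dissociation stress genes, which did not pass in all leukocytes, T cells or class M1. Ifitm3 was lower in 14 of 15 (-1.93 to 0.13), and Arhgap31 in 12 of 14 (-2.71 to 1.27). Cd200 was lower in 6 and higher in 3 of 9 (-5.15 to 1.196), with 1.196 in Tregs and 0.57 in T cells, neither of which passed. These sets overlap and share libraries, so they are not independent.

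Lists in other classes gave the following. Mitochondrially encoded genes were higher in B (median 0.61, adjusted p = 1.29e-07, adjusted p = 0.609 with an estimated correlation), DC (0.48, 0.000499, adjusted p = 0.795 with an estimated correlation) and M2 (0.60, 3.45e-06, adjusted p = 0.750 with an estimated correlation). NK/NKT had 0.25 (0.0385, adjusted p = 0.903 with an estimated correlation), pDC 0.53 (0.00132, adjusted p = 0.708 with an estimated correlation) and Cd8+ NKT 0.46 (0.0111, adjusted p = 0.843 with an estimated correlation). Teff 1 had 0.48 (0.00347, adjusted p = 0.827 with an estimated correlation), Teff 2 0.53 (3.61e-05, adjusted p = 0.755 with an estimated correlation) and Tregs 0.36 (0.0150, adjusted p = 0.846 with an estimated correlation). Leaving out each library in turn kept the mitochondrial call in B (0.45 to 0.79) and M2 (0.36 to 0.92) and lost it at least once in the others. Their medians ranged from 0.19 to 0.71 in DC, 0.0949 to 0.40 in NK/NKT, 0.0779 to 1.095 in pDC, 0.19 to 0.70 in Cd8+ NKT, 0.11 to 0.83 in Teff 1, 0.41 to 0.68 in Teff 2 and 0.15 to 0.58 in Tregs. Type I interferon response genes were lower in B cells for 18 of 18 members (median -0.77, adjusted p = 1.09e-06, adjusted p = 0.609 with an estimated correlation), 8 adjusted over the list alone, Xaf1 at 24.5 against 55.6 CPM among them. In M2 they were lower for 19 of 20 (median -0.58, 0.000359, adjusted p = 0.750 with an estimated correlation) and in Tregs for 9 of 10 (-0.61, 0.0150, adjusted p = 0.846 with an estimated correlation). In pDC they were lower for 6 of 8 (-0.83, 0.00819, adjusted p = 0.570 with an estimated correlation) and in Teff 2 for 8 of 8 (-1.19, 0.00204, adjusted p = 0.847 with an estimated correlation). All 5 interferon calls rested on WT replicate 2: without it they were lost, with medians of 0.00691 in B, 0.16 in M2, -0.000337 in Tregs, 0.28 in pDC and 0.0642 in Teff 2.

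Class M2 had higher complement and scavenger genes (7 of 9, median 0.52, adjusted p = 0.0395) and inflammatory genes (13 of 15, 0.30, adjusted p = 0.0102), both with adjusted p = 0.750 with an estimated correlation. Ptgs2, the prostaglandin synthase gene, stood at 1062 against 769 CPM there, and Pf4 at 27.5 against 11.5 CPM. Tregs had lower MHC class II genes (6 of 7 lower, median -0.60, adjusted p = 0.0150, adjusted p = 0.846 with an estimated correlation), with Cd74, the invariant chain, at 768 against 1688 CPM. NK/NKT had lower MHC class II genes (-0.49, 0.0385) and higher regulatory T cell genes (8 of 9, 0.59, adjusted p = 0.0349), both with adjusted p = 0.903 with an estimated correlation. Teff 1 had higher T cell receptor activation genes (10 of 11, 0.37, adjusted p = 0.00522), with Tnfrsf4 at 297 against 150 CPM, and lower cytotoxic genes (-0.33, 0.0379), both with adjusted p = 0.827 with an estimated correlation. DC had lower cell cycle genes (14 of 20 lower, -0.36, adjusted p = 0.000597, adjusted p = 0.795 with an estimated correlation), which rested on BTLA-KO replicate 1: without it the median was -0.13 (adjusted p = 0.781) and the test pointed up, and without BTLA-KO replicate 2 the median was -1.14. The chromosome 16 neighbours were lower in Teff 2 (5 of 5, -0.52, 0.00204, adjusted p = 0.755 with an estimated correlation), in Cd8+ NKT (7 of 9, -0.43, 0.0238, adjusted p = 0.843 with an estimated correlation) and in Cd4+ naive T (6 of 7, -0.25, 0.0134, adjusted p = 0.930 with an estimated correlation). They were also lower in DC (9 of 13, -0.19, 0.0315, adjusted p = 0.795 with an estimated correlation) and in B, where the median was -0.01 and the mean -0.62 (0.0206, adjusted p = 0.609 with an estimated correlation). Each list call in this paragraph was lost in at least 1 leave-out.

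The difference of the genotype effect between T cells and class M1 was tested directly, and 0 of 13074 genes passed in edgeR (603 with an unadjusted p under 0.05, DESeq2 not run). The smallest p values belonged to Arhgap31, with a difference of -1.40 (SE 0.18, adjusted p = 0.0852, log2 fold change -1.19 in T cells and 0.19 in class M1), the immunoglobulin gene Ighg2b (6.84, 0.0852) and the Notch target Hes1 (2.07, SE 0.29, 0.0852, 1.64 in T cells and -0.42 in class M1). Leaving out BTLA-KO replicates 1 and 2 gave 5 and 45 calls, and leaving out WT replicates 1 and 2 gave 12 and 7. Differences between T cells and class M1 for the gene lists were not tested.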

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

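The comparison of sex-linked genes between T cells and class M1 was made after the values were seen. Over the sex-linked genes, the BTLA-KO minus WT difference of the mean log2(CPM + 1) over members pointed down in T cells and up in class M1, and the first less the other was -0.1317. In T cells the BTLA-KO libraries stood at 4.97 and 4.84 and the WT libraries at 4.97 and 4.97, and in class M1 the BTLA-KO libraries stood at 4.53 and 4.42 against 4.41 and 4.41. Each BTLA-KO library lay below the WT mean in T cells and above it in class M1, and the difference between the classes was not tested. The list itself did not pass in T cells (adjusted p = 0.503) or class M1 (adjusted p = 0.655).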

How the results depend on the processing

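The alternatives were fixed before the data were examined, except the top-5% doublet score setting and all leukocytes without Kidney Cells, which were chosen after seeing the data. The cause was not tested for the changed counts. Leave-outs use fewer libraries, and the setting without a filter tests more genes. In that setting 67 genes passed in all leukocytes, 163 in T cells, 122 in B, 155 in DC, 189 in class M1, 69 in M2, 44 in NK/NKT, 148 in the T class, 36 in pDC, 3 in Cd4+ naive T, 23 in Cd8+ NKT, 27 in Cd8+ T, 17 in Teff 1, 25 in Teff 2, 41 in Tregs and 79 in the interaction. Of these calls, 0 in all leukocytes, 10 in T cells, 10 in B, 12 in DC and 4 in class M1 were of genes the filter leaves out. Most calls in these sets were thus of genes that were tested with the filter too.

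The DESeq2 Wald test called 41 genes in all leukocytes, 2 in T cells, 13 in B, 21 in class M1, 0 in NK/NKT, 2 in the T class, 1 in Cd8+ NKT, 0 in Cd8+ T and 0 in Teff 1. With the replicate number as a block the counts were 0 in all leukocytes, 3 in T cells, 20 in B, 18 in DC, 55 in M2, 0 in NK/NKT, 7 in the T class, 10 in pDC, 10 in Cd8+ NKT, 10 in Cd8+ T, 28 in Teff 1, 6 in Teff 2 and 32 in Tregs, and Btla in all leukocytes was -2.73 (adjusted p = 0.208, the highest over its alternatives, of which the DESeq2 test gave the lowest, 4.56e-41). Deviations of same-numbered libraries from their group means correlated at -0.08 to 0.02 across genes. This does not tell whether same-numbered libraries share a day, litter or batch, and the labels do not say. Scaling by library size alone gave 3 genes in B, 0 in pDC, 10 in Teff 2 and 1 list in Cd8+ T, which also had 1 under the block. Equal cell numbers per library gave 13 in B, 6 in DC, and 0 in NK/NKT, pDC, Cd8+ NKT, Cd8+ T and Teff 1. Without the top-5% doublet scores 0 genes passed in B, 1 in DC, 2 in M2 and 0 in pDC, and Gzmc in class M1 was -0.60. Leaving out called doublets was not run, since 3 of 20233 cells were called.

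An estimated correlation and fry each left 0 lists in all leukocytes, T cells, class M1 and the other classes with a list, and a prior count of 0.5 left 1 list in NK/NKT. With 2 libraries per group an estimated correlation and fry could pass hardly any list, so this loss decides nothing about single lists. Without the most populous class, the log2 difference was -0.0669 for the share of B among all leukocytes and 0.0318 for the share of Teff 4 among T cells, and with TMM across classes it was 0.0729 for the share of pDC among all leukocytes.

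Leaving out each library in turn assumes that a lone library varies like the others. Gene counts then ranged from 0 to 4 in all leukocytes, 0 to 45 in T cells, 76 to 114 in B, 11 to 208 in DC, 0 to 157 in class M1, 4 to 77 in M2, 15 to 40 in NK/NKT, 6 to 254 in the T class, 9 to 58 in pDC, 3 to 13 in Cd4+ naive T, 15 to 28 in Cd8+ NKT, 0 to 37 in Cd8+ T, 0 to 20 in Teff 1, 16 to 28 in Teff 2, 0 to 27 in Tregs and 5 to 45 in the interaction. Btla in all leukocytes ranged from -2.81 to -2.66. Log2 share differences ranged from -0.36 to 0.20 for DC, -0.78 to 0.27 for Granulocytes, -0.0447 to 0.78 for M2, -0.35 to 0.0718 for NK/NKT, -0.80 to 0.445 for pDC, -0.30 to 0.38 for Cd4+ naive T, -0.22 to 0.56 for Teff 1 and -0.22 to 0.24 for Teff 4.

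List medians whose direction turned, by sign or by the test, ranged as follows. In all leukocytes cytotoxic genes ranged from -0.46 to -0.0304, the type I interferon response from -1.07 to 0.17, inflammatory genes from -0.00738 to 0.52 and cell cycle genes from -0.41 to 0.0525. In T cells the interferon response ranged from -0.84 to 0.0704 and cell cycle genes from -0.0428 to 0.67, and in class M1 from -1.13 to 0.15 and -0.57 to 0.0826. In the T class the interferon response ranged from -0.75 to 0.0495, the median of cell cycle in T (all-cell annotation) from -0.0329 to 0.71 and T cell receptor activation genes from 0.0303 to 0.45. The interferon response ranged from -1.29 to 0.00691 in B, -0.90 to 0.16 in M2 and -1.63 to 0.0642 in Teff 2, and dissociation stress genes in Cd8+ NKT from -0.42 to 0.0717. B inflammatory genes ranged from -0.14 to 1.31, DC cell cycle genes from -1.14 to -0.13, the pDC interferon response from -1.13 to 0.28 and the median of mitochondrially encoded genes in pDC from 0.0779 to 1.095. Passing lists numbered 3 to 5 in B, 2 to 6 in DC, 2 to 6 in M2, 2 to 5 in NK/NKT, 1 to 9 in pDC, 2 to 6 in Cd4+ naive T, 0 to 7 in Cd8+ NKT, 0 to 5 in Cd8+ T, 3 to 8 in Teff 1 and 2 to 5 in Tregs.

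Over all alternatives, 64 of 169 gene counts and 83 of 135 list counts stayed within 1.5 times the main count, whichever genes or lists passed: the 1 gene that passed in T cells without WT replicate 1 was not the main one. Direction and side of the threshold were kept in 432 of 729 list tests, 493 of 593 values of named genes and 161 of 176 shares. Another 15 list tests, 1 named gene and 15 shares turned direction, and 282 list tests lost their call. Fewer genes had enough counts to be tested in classes of low depth, with 4785 in Teff 2 and 3868 in pDC against 14235 in all leukocytes.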

Other observations

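The 7 tests of explanations reported here were all chosen after the results were seen, while the list tests were fixed before the data were examined. Further lists passed in single classes. In pDC, inflammatory cytokines and NF-kB targets were higher for 8 of 9 members (median log2 0.53, adjusted p = 7.66e-05) and complement and scavenger genes for 4 of 5 (0.61, adjusted p = 0.00867), while lipid-associated genes were lower for 5 of 6 (-0.36, adjusted p = 0.0311), each with adjusted p = 0.570 with an estimated correlation. B cells had inflammatory genes with a median of 0.37 (12 of 14 higher, adjusted p = 0.0190), which turned to -0.14 without WT replicate 1 and -0.0439 without BTLA-KO replicate 1, and lower glycolysis genes (13 of 16 lower, -0.23, adjusted p = 0.0322) and nuclear respiratory chain genes (18 of 18 lower, -0.15, adjusted p = 0.0190), each with adjusted p = 0.609 with an estimated correlation. In DC the respiratory chain was lower for 16 of 18 (-0.14, adjusted p = 0.0315, adjusted p = 0.795 with an estimated correlation). Cd8+ NKT had lower interferon gamma response genes (12 of 15 lower, -0.31, adjusted p = 0.0255), of which Cxcl10 passed alone, and lower dissociation stress genes (-0.16, adjusted p = 0.0342), both with adjusted p = 0.843 with an estimated correlation. Tregs had lower dissociation stress genes (18 of 20 lower, median -0.24, adjusted p = 0.0150, adjusted p = 0.846 with an estimated correlation). Teff 2 had higher cell cycle genes (5 of 7, 0.23, adjusted p = 0.0243, adjusted p = 0.755 with an estimated correlation). Apart from the pDC inflammatory genes (medians 0.20 to 1.41), each of these calls was lost in at least 1 leave-out, and the dissociation stress median in Cd8+ NKT was 0.0717 without BTLA-KO replicate 2.

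Within class M1, the deposited cluster with the most macrophage markers (cluster 0, 769 CPM) made up 55.5% ± 3.54 of BTLA-KO and 48.1% ± 1.63 of WT cells (SD, n = 2, adjusted p = 0.467). Of the genes tested in the 4 clusters with enough cells, 1 passed, Btla in cluster 3, which carried dendritic cell markers (360 CPM for type 2 conventional dendritic cells).

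Genes around Btla on chromosome 16 differed more often than other genes in some sets of cells. Of the fixed neighbours, 6 of 19 in T cells (31.6%) had an unadjusted p under 0.05 against 5.70% of other genes (Fisher's exact p = 0.000501, adjusted p = 0.00376 over 15 sets), and all leukocytes passed too (adjusted p = 0.0103). That is more than chance gives if genes vary independently, but all genes come from the same 4 libraries, so chance is not excluded. The list test fixed beforehand, which asks for a shared direction, did not pass for these neighbours in T cells or all leukocytes. The T class, which shares most cells with T cells, passed, while the other 12 sets did not, at adjusted p values of 0.106 to 0.393. In all leukocytes 10 of 54 genes between 2 and 10 Mb from Btla (18.5%) had an unadjusted p under 0.05 against 8.59% on other chromosomes (Fisher's exact p = 0.02351), but not against the rest of chromosome 16 (12.6%, p = 0.282), which itself differed from other chromosomes (p = 0.01055), and 0 of 9 genes at 1 to 2 Mb had one. Differing DNA linked to Btla may contribute, but it cannot be told apart from other reasons, such as an effect of the altered locus on its neighbours.

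Mitochondrially encoded genes were higher in BTLA-KO in all leukocytes, a call lost with an estimated correlation (adjusted p = 0.781 with an estimated correlation). If damaged cells rich in these transcripts were the cause, the lower end of the distribution was predicted to be alike. In class M1 the lower quartile of the mitochondrial share was 0.175% and 0.554% in BTLA-KO against 0.0688% and 0.0738% in WT, a ratio of 5.114. The difference among kept cells was thus not confined to the upper end. This does not decide whether damaged cells contributed, since many added cells rich in these transcripts would also raise the lower quartile. The size of the ratio depends on the WT quartiles, which lie among cells nearly free of these transcripts. Barcodes at 5% or more, which were not kept, were 9.29% and 7.45% of those deposited for BTLA-KO against 7.12% and 6.97% for WT. Cells with under 0.1% were 20.4% and 12.02% of BTLA-KO and 29.1% and 27.0% of WT, and without them the log2 ratio of the mitochondrial share went from 0.55 to 0.31 in all leukocytes and from 0.43 to 0.16 in T cells, but the cut, chosen after the values were seen, is on the share itself, so fewer such cells and a general rise cannot be told apart. An effect of BTLA inside the cells that express it may give a smaller change where Btla is low, and the median in NK/NKT (5.15 CPM Btla in WT) less that in DC (103 CPM) was -0.2361. Cd8+ T, at 4.37 CPM, had 0.25. Yet M2, at 6.58 CPM, had 0.60, and Cd4+ naive T, at 43.8 CPM, had 0.28, so this too cannot be told apart. A difference in handling between the libraries, for which the labels give no batch, stays open.

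In T cells, cytotoxic genes were lower and type 2 and regulatory T cell genes higher in BTLA-KO, calls that were lost with an estimated correlation (adjusted p = 0.656 for cytotoxic genes and 0.738 for the others) and under fry, and a shift in T cell class shares may account for part of this. With class shares held fixed, 18.81% of the cytotoxic difference was left (from -0.38 to -0.07 on the log2 scale), which is consistent with a shift in shares as most of it. For type 2 genes 51.29% was left (from 0.94 to 0.48) and for regulatory T cell genes 43.79% (from 0.53 to 0.23), so shares and changes within classes cannot be told apart for these. The share differences themselves did not pass, and the sources used here do not say which genes defined the deposited classes.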
